A study of Mus musculus with 2 samples.

How the data were processed

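H3K4me3 was measured by chromatin immunoprecipitation and sequencing in pooled midbrain tissue of B6NCrl mouse embryos at 10.5 days, with 69 embryos in replicate 1 and 51 in replicate 2. The labels give 1 group of 2 biological replicates, numbered in the labels, so the comparisons were those between replicates, with random placement, and between fixed sets of genes. The labels name fragments of a selected size range and a low-input protocol, and the tissue was fixed and sonicated. Aligner, peak caller and calling threshold are not given in the sources used here.

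The authors deposited 4 lists of narrow peaks in mm10. Per the file headers, each replicate list came from that replicate's alignments and 1 control, the pooled list from the alignments of both replicates and their controls, and the replicated list from the pooled list and both replicate lists. The rule by which replicated peaks were chosen is not stated. As tested on the files, each of the 30223 replicated peaks is a peak of the pooled list, and 88.7% of them overlap peaks of both replicates. Each peak has a position, a signal value, a −log10 p, a −log10 q and a summit, all deposited by the authors. The signal value was computed by the authors over a control, on a scale that is not stated; it had been assumed to be a fold enrichment when the tests were set, and was then treated as a signal. It served only to describe, rank and filter peaks within a list and was never read as a change between replicates. The lists give no read counts, so the depth of each replicate is unknown and no precision can be derived from it. The longer list of replicate 1 may reflect depth or threshold as well as tissue, since the number of peaks a caller finds moves with both.

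Gene positions and start sites were taken from the GENCODE M21 comprehensive annotation of the primary assembly, with 55413 genes, 21938 of them protein-coding, and 132721 start sites. It is of the same build as the peaks, all of which lie within the chromosome lengths. The genome sequence of that build was used for the ratio of observed to expected CpG. The ratio covered 500 bp on either side of the gene's 5′ end or, for peaks, of the summit. Shares by CpG ratio counted only replicated peaks within 1 kb of the 5′ end. Peaks on unplaced scaffolds were left out of the comparisons with random shifts and of those with genes, and stayed in the counts per list, the quartiles, the peaks with and without a partner and the correlation across peaks. A promoter was the window of 1 kb on either side of any start site of a gene, and a gene was called marked when a replicated peak overlapped that window. Peaks whose gaps were at most 1 kb were merged into domains, and the width of a gene was that of the widest domain at its promoter. Widths are given per replicate and as mean ± SD over both. Peaks overlapping by at least 1 bp counted as shared.

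Overlaps and the promoter share were compared with 100 random circular shifts along each of the 21 main chromosomes, so the smallest p is 0.0099. Shares were compared with two-sided Fisher's exact tests, and median widths with two-sided permutation tests of 100000 resamples, whose smallest p is 1e-05. Both were adjusted by the Benjamini-Hochberg method, over 19 lists for shares and over the 15 lists with at least 5 marked genes for widths, at a threshold of 0.05. Binomial intervals are exact at 95% and cover counting error only. Summit distances were taken from the 5′ end of the gene to the nearest summit of a peak within 1 kb of it. Rank agreement is given as Pearson and Spearman correlations of log2 signal values. With 1 group of 2 replicates no test between groups was possible.

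The tests, 18 gene lists and the rule for named genes were fixed before the data were examined. The lists held 305 genes, of which 304 matched the annotation (Ahsp did not), and all genes whose symbols begin with Olfr, Taar, Vmn1r or Vmn2r formed the list of 1481 chemosensory receptors. Named genes were the 2 marked genes with the widest domain and up to 2 unmarked genes in alphabetical order from each list, the 10 coding genes with the widest domains, the 5 with the highest signal value in the pooled list, the 4 strongest promoters called in each replicate alone, and the 5 strongest replicated peaks more than 10 kb from any start site. Genes named outside this rule are said to be.

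Alternatives fixed with the tests were a −log10 q of at least 5, an overlap of at least 50% of the peak, −log10 p in place of the signal value, windows of 500 bp and 2 kb, each replicate alone, the pooled list, no merging, merging across 3 kb, a CpG ratio of 0.4, and genes with 1 start site and no other within 2 kb. Added after the data were seen were GENCODE's basic transcript set, genes called in both replicates, peaks with their summit within 1 kb of a start site, and no merging for the comparisons of a list with another.

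Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The tests were first tested on simulated data. Each planted list held 20 genes, over a background of 60% marked, and resamples were fewer than in the real tests. Lists planted as all marked, as 10% marked and as 4 times as wide were called in 20 of 20 rounds each. Lists drawn like other genes were called in 0 of 20 rounds, for share and for width. Smaller lists and smaller effects, which occur among the results, were not simulated. Simulated genes were marked and given widths independently of each other, so false calls under dependence between genes were not tested. An overlap planted at 70.2% of 30210 intervals came out at 70.6%, a brute-force search gave the same answer for 300 of 300 intervals, and summits planted 100 bp downstream of 21938 starts were found at a median of 100 bp.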

Results

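Trimethylation of lysine 4 on histone H3 (H3K4me3), the histone mark of promoters, was mapped by chromatin immunoprecipitation and sequencing in the embryonic mouse midbrain. The tissue came from B6NCrl embryos of both sexes at 10.5 days of development, when neural progenitors line the midbrain and the first neurons appear. The single group held 2 biological replicates, each a pool of dissected midbrains: 69 embryos for replicate 1 and 51 for replicate 2. The list of replicate 1 held 48331 peaks covering 54.2 Mb, and that of replicate 2 held 34732 peaks covering 42.9 Mb (mean 41531.5 ± 9616 peaks, SD, n = 2). A pooled list of 47382 peaks and a replicated list of 30223 peaks covered 57.1 and 52.5 Mb. Only peak lists were analysed, so the sequencing depth behind them is unknown. All coordinates are in mm10.

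The 2 replicates were compared first, since the design has no other group. Strong peaks were found in both midbrain pools, and the peaks that differed were weak and narrow ones, most of them in replicate 1. In the top quartile of signal values, 100% of replicate 1 peaks and 100% of replicate 2 peaks were overlapped in the other replicate. In the bottom quartile the share was 13.8% for replicate 1 and 71.6% for replicate 2. Over the main chromosomes, 58.6% of replicate 1 peaks (28317 of 48317) overlapped a replicate 2 peak, and 91.4% of replicate 2 peaks (31747 of 34719) overlapped a replicate 1 peak. Random shifts of the other list along each chromosome gave 3.08% and 4.10% on average and at most 3.67% and 4.76% (permutation p = 0.0099 for each, the smallest that 100 shifts can give). The overlap rose to 81.6% and 98.0% when peaks were restricted to a −log10 q of at least 5. In length, the shared 41.0 Mb made up 75.7% of replicate 1's covered sequence and 95.7% of replicate 2's.

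**Figure D1:**
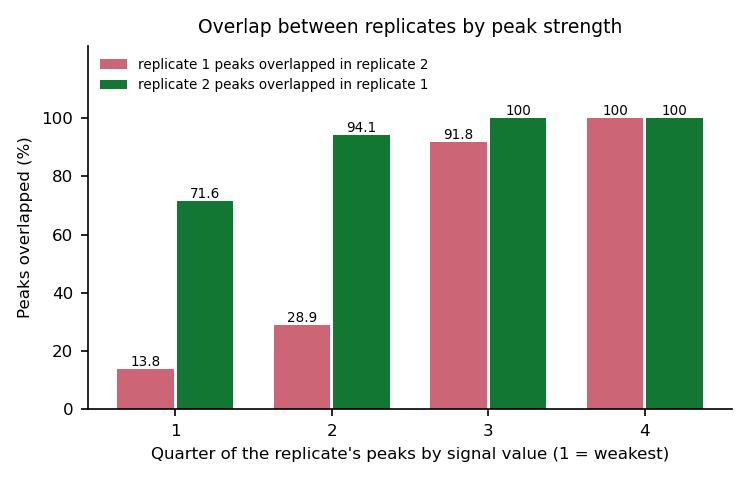
Share of each replicate's H3K4me3 peaks overlapped by at least 1 bp in the other replicate (y axis, percent), by quartile of that replicate's peaks in the authors' signal value (x axis, 1 = weakest). Red bars are replicate 1 peaks and green bars are replicate 2 peaks; the shares run from 13.8% to 100% in replicate 1 and from 71.6% to 100% in replicate 2.

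The 20002 replicate 1 peaks without a partner had a median width of 234 bp and a median signal value of 2.74, and 22.4% of them lay at promoters. The 28329 replicate 1 peaks with a partner had medians of 1376 bp and 17.6, and 61.3% lay at promoters. The 2974 replicate 2 peaks without a partner were likewise weak and narrow, with a median width of 207 bp, a median signal value of 3.04 and 21.8% at promoters. Signal values, which are the authors' own, ranked overlapping peaks alike in both replicates, with a Spearman correlation of 0.912 and a Pearson correlation of 0.933 on the log2 scale across 28329 pairs. Across the 14717 protein-coding promoters called in both replicates, the Spearman correlation was 0.775 for signal value and 0.901 for domain width. These correlations run across peaks and genes, which are not independent replicates, so no p-value was attached.

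H3K4me3 peaks in the midbrain lay at gene starts far more often than random placement gives. Of the 30210 replicated peaks on the main chromosomes, 17667 (58.5%) lay within 1 kb of an annotated start site, against 10.7% on average and 11.9% at most when the list was shifted at random (permutation p = 0.0099, the smallest possible). The share was 54.6% in replicate 2 and 45.2% in the longer list of replicate 1, and 45.5% in the pooled list (permutation p = 0.0099 for each). Promoter peaks of the replicated list were broad and strong, with a median width of 2145 bp and a median signal value of 40.8. Another 5585 peaks (18.5%) lay in introns, 1465 (4.85%) in exons and 5493 (18.2%) between genes, and these 12543 peaks outside promoters had a median width of 691 bp and a median signal value of 4.25. The ratio of observed to expected CpG was at least 0.6 in 61.7% of promoter peaks and in 7.42% of the peaks outside promoters.

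Most protein-coding promoters carried the mark. A replicated peak lay within 1 kb of a start site of 14789 of 21938 protein-coding genes, which is 67.4% (exact 95% binomial interval 66.8 to 68.0%, counting error only). The share was 68.3% in replicate 1 and 67.3% in replicate 2 (mean 67.8% ± 0.725, SD, n = 2). Genes for long noncoding RNAs were marked in 28.3% of cases (2874 of 10155, interval 27.4 to 29.2%). The odds ratio between both kinds of gene was 5.24 (two-sided Fisher's exact test, p below 1e-300). No adjustment was made for the number of start sites per gene or for promoters shared between both kinds. Genes are not independent replicates, so this and the other tests across genes compare sets of genes within these peak lists.

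Genes that were CpG-rich at their 5′ end almost all had a replicated peak there, and CpG-poor ones mostly did not. Protein-coding genes were split by the observed to expected CpG ratio over 500 bp on either side of their 5′ end. Only replicated peaks within 1 kb of that end were counted. This gave 14022 genes with a peak, against 14789 marked at any start site. With a ratio of at least 0.6, 9939 of 10078 genes (98.6%) had such a peak. Among those with a lower ratio, 4083 of 11860 (34.4%) had one. The difference was 64.2 percentage points, with an odds ratio of 136 (Fisher's exact test, p below 1e-300).

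Genes that pattern the midbrain and the isthmus, the organizer at its border with the hindbrain, had the widest H3K4me3 domains of the gene lists examined by list median, although the widest single domains lay in the neural progenitor list. All 17 were marked, against 67.4% of other protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00283 over 19 lists). Their median domain, with neighbouring peaks merged across gaps of up to 1 kb, was 16229 bp wide, 6.13 times the 2646 bp of other marked genes (permutation test, adjusted p = 3.75e-05 over 15 lists, from the smallest p that 100000 resamples can give). Otx2, the homeobox gene needed for forebrain and midbrain identity, lies on chromosome 14 at 48657677 to 48673819 on the minus strand. A single peak from 48654258 to 48675987 covered this whole gene, and its domain was 21387.5 ± 418 bp wide (SD, n = 2). Meis2, which encodes a homeodomain partner of Otx2 in the midbrain roof, had a domain of 18152 ± 4309 bp. The list median was 16198 bp in replicate 1 and 11097 bp in replicate 2, where other marked genes had 2748 and 2284 bp. Without merging it was 8026 bp against 2524.5 bp (permutation test, adjusted p = 5e-05). The higher marked share was no longer called when the summit had to lie within 1 kb of a start site (Fisher's exact test, adjusted p = 0.122). The shares of this and the other lists were not matched on CpG ratio. Of all CpG-rich genes, 98.6% had a peak at their 5′ end.

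Neural progenitor genes were also all marked (20 of 20, Fisher's exact test, adjusted p = 0.00189) and had wide domains. The median was 8025.5 bp, 3.03 times that of other genes (permutation test, adjusted p = 3.75e-05). Sox2, a transcription factor that maintains neural progenitors, lies on chromosome 3 at 34650405 to 34652461, and its domain of 29307.5 ± 7325 bp (SD, n = 2) was the widest of this list. Pax6, a homeobox gene of dorsal and lateral progenitors in the brain, followed with 20627.5 ± 4979 bp. The widest single peaks were 22523 bp at Sox2 and 15980 bp at Pax6. The list median was 9270 bp in replicate 1, 5540.5 bp in replicate 2 and 5947 bp without merging.

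Genes of the ventral midbrain and the dopaminergic lineage were mostly marked, and their domains were wide by the median but varied from gene to gene. Of 16 genes, 14 were marked, a share of 87.5% that was not distinguished from other genes (Fisher's exact test, adjusted p = 0.17). Their median domain of 8299.5 bp was 3.14 times that of other genes (interquartile range 2650.25 to 12144 bp, permutation test, adjusted p = 3.75e-05) and measured 8482 and 7209.5 bp in replicates 1 and 2 and 5508.5 bp without merging. Foxa1, a forkhead factor of the floor plate, had a domain of 16514 ± 17.0 bp (SD, n = 2), and Nkx2-2, a homeobox gene of ventral progenitors, one of 16461.5 ± 1961 bp. The widest single peaks were 13066 bp at Foxa1 and 6705 bp at Nkx2-2. Domains in the replicated list were narrow at Slc6a3, the dopamine transporter (1305 bp), and Slc18a2, the vesicular monoamine transporter (1587 bp), which were named after their values were seen. The unmarked genes were Aldh1a1, a retinaldehyde dehydrogenase of a subset of dopaminergic neurons, and Th, the rate-limiting enzyme of dopamine synthesis. Aldh1a1 had no promoter peak in either replicate, and Th had a single peak of 252 bp in replicate 1 with a signal value of 1.91.

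Genes of early postmitotic neurons and genes of mature synapses were all marked (18 of 18 in each list, Fisher's exact test, adjusted p = 0.00283 for each), and of these lists the early one alone passed the width test. Early neuronal genes had a median domain of 4640.5 bp, 1.75 times that of other genes (permutation test, adjusted p = 0.000225), with 5462.5 bp in replicate 1 and 4110 bp in replicate 2. Gata3 and Gata2, zinc finger factors of GABAergic neurons in the midbrain, had domains of 13937 ± 5189 and 8431.5 ± 4301 bp (SD, n = 2). The Gata3 domain held start sites of 3 coding genes, and its widest single peak was 4258 bp. At Gata2 the widest single peak was 5567 bp. Mature synapse genes had a median of 2183.5 bp, which was not distinguished from other genes (permutation test, adjusted p = 0.227). The widest in the replicated list were those of Bdnf, a neurotrophin regulated by activity, with 5633 ± 134 bp, and of Grin2a, a subunit of the NMDA receptor, with 3853 ± 8.49 bp. The difference between the early and the mature list was not tested. With merging across gaps of up to 3 kb the early neuronal median was 7366.5 bp, and the higher marked share of this list was no longer called when the summit had to lie within 1 kb (Fisher's exact test, adjusted p = 0.204).

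Forebrain patterning genes were marked in the midbrain as well, with domains narrower by list median than those of the midbrain and isthmus list. All 18 had a replicated promoter peak (Fisher's exact test, adjusted p = 0.00283; 0.0856 when the summit had to lie within 1 kb), and their median domain of 5245 bp was 1.98 times that of other genes (permutation test, adjusted p = 3.75e-05). The median was 5800.5 bp in replicate 1, 4495.5 bp in replicate 2, 3429 bp without merging and 6860.5 bp with merging across 3 kb. Lhx2 and Six3, homeobox genes of the anterior forebrain and eye field, had domains of 11346 ± 4711 and 10834.5 ± 5682 bp (SD, n = 2). Their widest single peaks were 8599 and 7613 bp. Set directly against each other, the midbrain and isthmus list and the forebrain list had the same marked share (Fisher's exact test, p = 1). Their median widths differed by 10984 bp (two-sided permutation test, p = 8e-05). The difference was 6601.5 bp without replicate 1 (permutation p = 0.00056) and 4597 bp without merging (p = 0.00119). This direct comparison was not matched on CpG count or signal. Lists of other genes matched on both had typical medians of 4241 bp for the midbrain and isthmus list and 2981 bp for the forebrain list. The lists are also not exclusive by region, since Otx2 of the midbrain list is needed for forebrain identity too.

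Hox genes, which specify position along the axis behind the midbrain, had narrow domains where they were marked. Of paralogue groups 1 to 5, 10 of 15 genes (66.7%) were marked, and of groups 6 to 13, 13 of 24 (54.2%), neither share being distinguished from other genes (Fisher's exact test, adjusted p = 1 and 0.227). The median domains of 1055 and 1049 bp were 0.399 and 0.396 times that of other marked genes (permutation test, adjusted p = 0.0106 and 0.00476). They were 1097 and 889.5 bp in replicate 1 and 937 and 547 bp in replicate 2. Hoxa1, expressed in the early hindbrain, had a domain of 1609 ± 164 bp (SD, n = 2), and Hoxd1, its paralogue in the Hoxd cluster, one of 1494.5 ± 12 bp. Hoxd8 had 1428.5 ± 87.0 bp, and Hoxa13, a gene of the posterior end of the axis, 1375.5 ± 213 bp. Hoxa2 had a promoter peak in replicate 1 only, with a signal value of 3.13, Hoxa11 in replicate 2 only, with 2.89, and Hoxa3 and Hoxa9 in neither. Replicated peaks did lie inside the Hoxa3 gene, among them those at 52172207 to 52173063 and 52175529 to 52176120, but more than 1 kb from its annotated start sites. The anterior and posterior Hox lists did not differ detectably from each other in share (Fisher's exact test, p = 0.517) or width (permutation test, p = 0.999). In the pooled list, which holds weaker peaks, the marked shares of both Hox lists lay above that of other genes by 18.2 and 14.8 percentage points, again without a call.

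**Figure D2:**
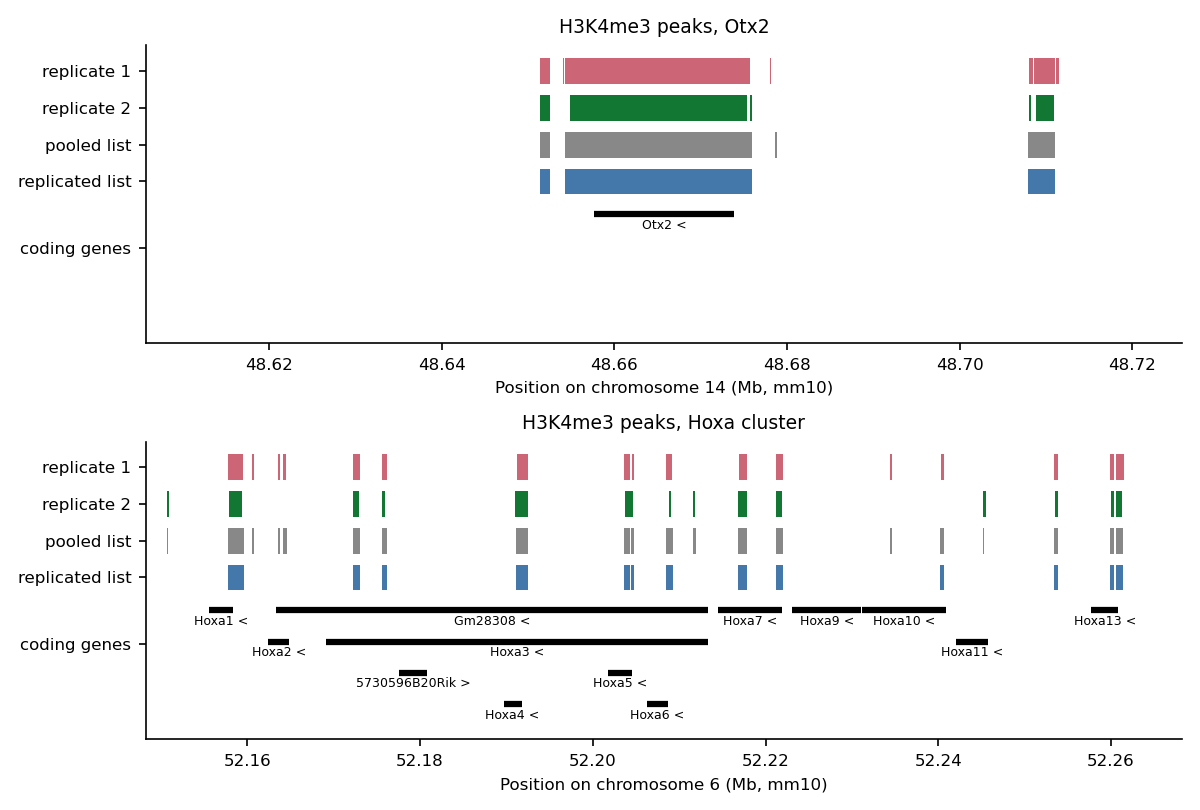
Peaks of the 4 lists (colored blocks, labelled at the left) and protein-coding genes (black bars, with < or > for the strand) over 120.0 kb around Otx2 on chromosome 14 and over the Hoxa cluster on chromosome 6, with position in Mb of mm10 on the x axis. The replicated peak from 48654258 to 48675987 spans the whole Otx2 gene, while the Hoxa cluster carries separate short peaks, the widest of them at Hoxa1 (1842 bp).

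Markers of other cell types that dissected midbrain could hold were marked to different extents. Endothelial genes were marked in 13 of 15 cases (adjusted p = 0.211) and mesenchyme and neural crest genes in 16 of 19 (adjusted p = 0.197), neither share being distinguished from other genes by Fisher's exact test. Egfl7, secreted by endothelial cells, had a domain of 4176.5 ± 971 bp (SD, n = 2), and Esam, an endothelial adhesion molecule, one of 4858.5 ± 334 bp. The endothelial genes Emcn and Tie1 were unmarked, although Tie1 had a peak with a signal value of 3.11 in replicate 1. The median width of endothelial domains was 2301 bp (permutation test, adjusted p = 0.462). Mesenchymal domains had a median of 4576.5 bp, 1.73 times that of other genes (permutation test, adjusted p = 0.000514), but this call ended without merging, at 2765.5 bp (adjusted p = 0.476). Pdgfra, a growth factor receptor of mesenchyme, had a domain of 9229.5 ± 224 bp and Prrx1, a homeobox gene of head and limb mesenchyme, one of 7028.5 ± 85.6 bp. Their widest single peaks were 4639 and 5009 bp. The collagen gene Col3a1 had a peak in replicate 2 only, with a signal value of 3.15, and Lum, which encodes the matrix protein lumican, had none.

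Red cell and glial genes were marked in part. Of 16 erythroid genes, 7 were marked (43.8%, Fisher's exact test, adjusted p = 0.102), with a median domain of 2702 bp (permutation test, adjusted p = 0.923) that fell to 1254 bp without merging (adjusted p = 0.0295). The medians were 1786 bp in replicate 1 and 1991 bp in replicate 2, below the 2751 and 2286.5 bp of other genes but without a call (permutation test, adjusted p = 0.129 and 0.606). Tal1, a factor of blood and of midbrain neurons, had the widest at 8202 ± 140.0 bp (SD, n = 2), followed by the erythropoietin receptor gene Epor at 3341.5 ± 238 bp. Klf1, the erythroid Kruppel-like factor, was named after its values were seen: its promoter peak had signal values of 37.5 in replicate 1 and 45.0 in replicate 2. Alas2, the first enzyme of heme synthesis in red cells, had no peak, and Gata1 had one of 2.43 in replicate 1 only. The adult globin genes, which exist as near-identical copies, are uncertain. Of 15 glial genes, 10 were marked (Fisher's exact test, adjusted p = 1), with a median domain of 1839.5 bp (permutation test, adjusted p = 0.116; 1574 bp and 0.0356 without merging). Olig2, a factor of ventral progenitors before it marks oligodendrocytes, had a domain of 10323 ± 816 bp and Slc1a2, the main glial glutamate transporter, one of 5029.5 ± 3101 bp. The astrocyte filament gene Gfap had a peak of 2.56 in replicate 1 only, and the myelin gene Mag had none.

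Genes of myeloid cells, liver and germline were largely unmarked. A replicated promoter peak was found at 1 of 14 myeloid and microglial genes (7.14%, Fisher's exact test, adjusted p = 2.87e-05), 1 of 15 liver genes (6.67%, adjusted p = 1.5e-05) and 2 of 15 germline genes (13.3%, adjusted p = 0.000113). The marked myeloid gene was Tmem119, a surface marker of microglia, whose domain of 1305.5 ± 9.19 bp (SD, n = 2) had signal values of 5.12 and 5.35. Aif1, which encodes the microglial protein Iba1, had weak peaks of 2.61 and 3.15 in both replicates and none in the replicated list, and the complement gene C1qa had one of 2.91 in replicate 1. Replicate 1 alone marked 3 liver and 4 germline genes, and replicate 2 alone 0 and 3, with lower shares called in each (Fisher's exact test, adjusted p at most 0.00365). In replicate 1 alone, 4 myeloid genes were marked, and their share differed from that of other genes by −39.8 in place of −60.3 percentage points (Fisher's exact test, adjusted p = 0.00506). The marked liver gene was Apoa1, the main protein of high-density lipoprotein, whose peak had its summit 1548 bp from the start site and reached the promoter window in replicate 1 only; Afp and Ahsg, genes of fetal liver plasma proteins, had none. The marked germline genes were Dazl, an RNA-binding protein of germ cells, with 1128.5 ± 54.4 bp, and Tdrd1, of the piRNA pathway, with 392.5 ± 179 bp. Acrv1, of the sperm acrosome, had no peak. These shares were not matched on CpG ratio, and 34.4% of all CpG-poor genes had a peak at their 5′ end. The unmarked Aif1, C1qa, Afp, Ahsg and Acrv1 had CpG ratios of 0.0233 to 0.393, but the unmarked germline gene Ddx4 had 0.742.

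Muscle and pluripotency genes had narrow domains in the replicated list, by calls that several other settings ended. Of 17 muscle and heart genes, 8 were marked (47.1%, Fisher's exact test, adjusted p = 0.17), with a median domain of 1220.5 bp, 0.461 times that of other genes (permutation test, adjusted p = 0.0261). The widest in the replicated list were those of Ckm, muscle creatine kinase, with 2612 bp, and Myod1, the myogenic master factor, with 2376 bp. Over the replicates they measured 1420.5 ± 564 and 2229.5 ± 114 bp (SD, n = 2), and the Ckm summit lay 93 bp from the start of the neighbouring Klc3. The actin gene Acta1 had no peak and Actc1 had one of 2.39 in replicate 1. The lower share was called under several other settings (Fisher's exact test, adjusted p = 0.0148 with a window of 500 bp and 0.0138 without replicate 1), and the width call ended with merging across 3 kb (permutation test, adjusted p = 0.0963) and with the basic transcript set (0.051). Of 14 pluripotency genes, 10 were marked (71.4%, Fisher's exact test, adjusted p = 1), with a median domain of 1372.5 bp (permutation test, adjusted p = 0.025). This call ended under 4 of 6 alternatives, with adjusted permutation p of 0.0674 without replicate 1, 0.052 with merging across 3 kb, 0.0699 with a −log10 q of at least 5 and 0.0791 with the basic transcript set. Lin28a and Sall4, which encode regulators also active in early embryonic tissues, had wide domains of 7745.5 ± 3181 and 7073.5 ± 1490 bp, while Dppa4 and Dppa5a had no peak.

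The reference lists were marked in full and almost not at all. All 18 housekeeping genes were marked (Fisher's exact test, adjusted p = 0.00283), with a median domain of 4995.5 bp, 1.89 times that of other genes (permutation test, adjusted p = 6e-05). The widest of them, at Eef2, a translation elongation factor, and Rps18, a ribosomal protein, measured 10103.5 ± 3542 and 9823.5 ± 3504 bp (SD, n = 2), each with start sites of 3 coding genes. Their widest single peaks were 3541 and 4560 bp. Of the 1481 chemosensory receptor genes, chosen beforehand as a reference presumed silent outside sensory tissue, 4 were marked (0.270%, odds ratio 0.00104 by Fisher's exact test). The widest, at Vmn1r4, a vomeronasal receptor gene, measured 3195.5 ± 146 bp and had its summit 49 bp from the start of Nt5c3, a nucleotidase gene. Olfr94 had a domain of 1375 ± 45.3 bp. The other marked receptor genes, Olfr1033 and Olfr658, were named after their values were seen and had peaks of 373 and 597 bp. Olfr1 and Olfr10 had none.

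**Figure D3:**
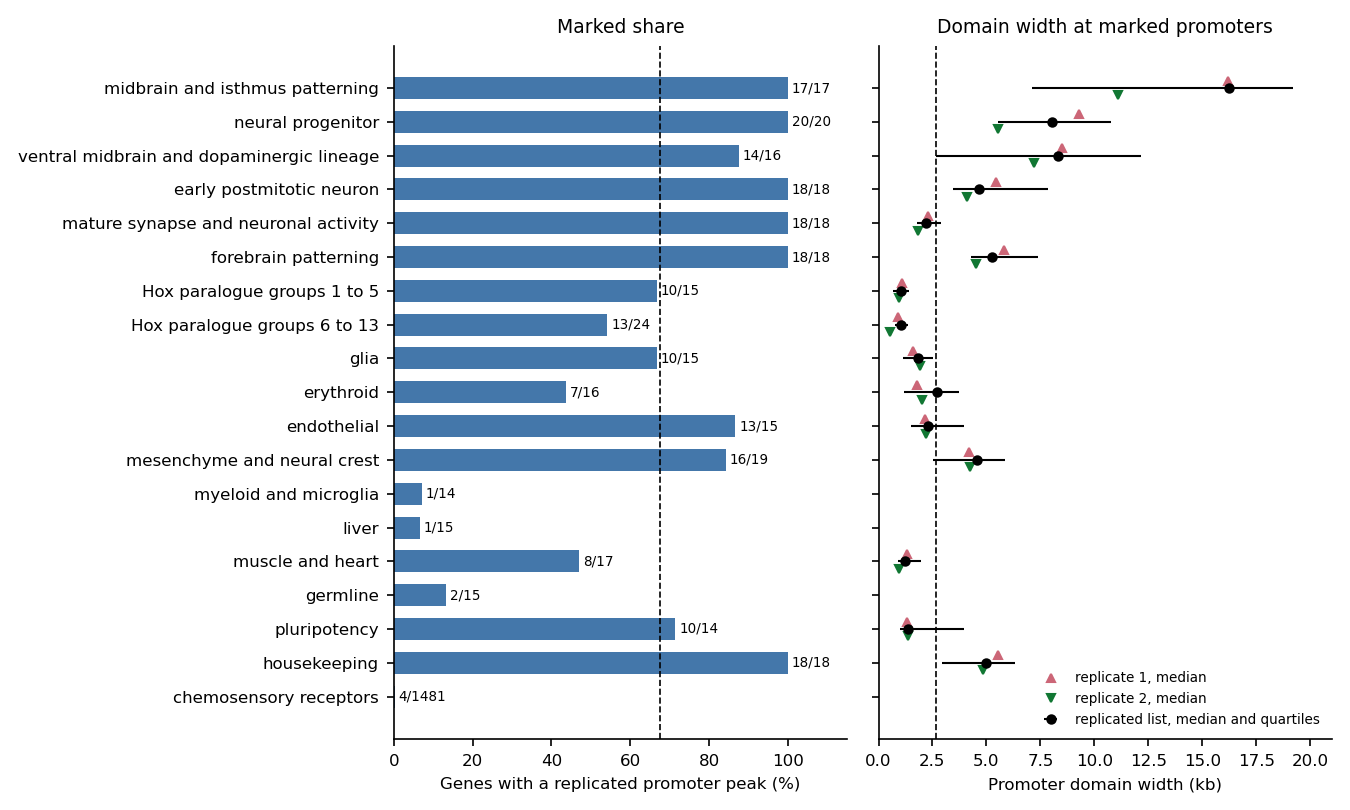
Left, share of each gene list with a replicated H3K4me3 peak within 1 kb of a start site (bars, percent, with marked and total genes; dashed line, all protein-coding genes). Right, promoter domain width in kb for lists with at least 5 marked genes: black points and lines are the median and quartiles over the genes of the replicated list, triangles are the medians of replicate 1 (upward) and replicate 2 (downward), and the dashed line is the median of all marked protein-coding genes. Midbrain and isthmus patterning genes had the widest median, 16229 bp, and the Hox lists the narrowest, 1055 and 1049 bp.

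Across all protein-coding genes, the widest domains were of differing make. The widest, 63033 bp on chromosome 10 from 80134724 to 80197756, arose by merging over a gene-dense stretch and held start sites of 6 coding genes, 1600002K03Rik, Atp5d, Cbarp, Cirbp, Efna2 and Midn. It was 65886 bp wide in replicate 1 but fell apart in replicate 2, where the domains of these genes measured 4210 to 11507 bp. Pou3f3, a POU-domain factor of neural progenitors, was covered by a single replicated peak of 31473 bp, and its domain of 31304 ± 132 bp (SD, n = 2) was alike in both replicates. Nr2f1, a nuclear receptor of the developing brain, had a domain of 29965.5 ± 16824 bp, with 41862 bp in replicate 1 and 18069 bp in replicate 2, and Sox2 ranked beside it. The widest single peak at Nr2f1 was 16613 bp. A930004D18Rik had a domain of 26750 ± 4552 bp that held start sites of 3 coding genes.

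The highest signal values in the pooled list lay at promoters of genes other than the patterning genes above. Atxn2l, which encodes a stress granule protein, led with 74.1, followed by Eif1b, a translation initiation factor, with 73.5, and Msl1, of a histone acetyltransferase complex, with 72.9. Hnrnpul2, which encodes a nuclear RNA-binding protein, and Ttc9c shared a peak of 72.8, with its summit 404 bp from the start of Hnrnpul2 and 1343 bp from that of Ttc9c. The domain at Atxn2l was 3541.5 ± 613 bp wide (SD, n = 2) and that at Eif1b 3086 ± 158 bp.

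Few promoters were called in a single replicate. Of the protein-coding genes, 14717 had a promoter peak in both replicates, 273 in replicate 1 only and 48 in replicate 2 only. The strongest ones in replicate 1 were those of Sftpc, a lung surfactant protein (signal value 48.8), AC141477.1 (48.3), Rap2b, a small GTPase (45.4), and Mia, a secreted protein of cartilage (40.6). Each was the edge of a peak centred outside the window that reached it in replicate 1 only. The summits lay 2181 to 2620 bp from the gene's own start. For Sftpc the summit was 223 bp from the start of Bmp1, a procollagen proteinase. At Rap2b the replicated peak lay inside the gene itself, and the nearest coding start, that of B430305J03Rik, was 1693 bp from its summit. Of the 273 genes, 254 had no overlapping replicate 2 peak even outside the window, and these had a median signal value of 2.88 and a highest of 5.45. Of the 48 genes called in replicate 2 only, 46 had none in replicate 1. The strongest of the 48 were Gsg1, a germ cell gene (7.45), Pcdhgb2, a clustered protocadherin (5.49), the germline gene Ddx4 and Eras, a Ras gene of embryonic stem cells (4.86 each).

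Some strong peaks lay far from any start site of the annotation used. Of the 5 strongest, described here, 3 had a start site of another annotation, RefSeq, within 1 kb. Of the replicated peaks, 5625 (18.6%) were more than 10 kb from the nearest start site, and the 5 with the highest signal values were all called in both replicates. The strongest was on chromosome 4 at 46304010 to 46305939, in an intron of the noncoding gene Gm12446, with a signal value of 55.8 and an observed to expected CpG ratio of 1.00; the nearest coding start was that of Foxe1, 38512 bp away. On chromosome 14, a peak at 34548228 to 34549974 with a signal value of 55.2 lay in an intron of Ldb3, a gene of the muscle Z-disc. On chromosome 18, intergenic peaks at 23309587 to 23311329 (52.7) and 75342038 to 75343852 (52.0) lay 104514 bp from the start of Dtna and 24739 bp from that of Smad7. On chromosome 1, an intergenic peak at 165280778 to 165283924 (52.6) lay 13710 bp from the start of Gpr161. Their CpG ratios were 0.672 to 1.00.

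H3K4me3 summits lay just downstream of gene starts. Over 14022 protein-coding genes with a peak at their 5′ end, the nearest summit was a median of 254 bp downstream of the start (interquartile range 140 to 436 bp). The median was 264 bp in replicate 1 and 239 bp in replicate 2 (mean 251.5 ± 17.7 bp, SD, n = 2). The summit was downstream in 85.7% of genes (12010 of 14017 with a nonzero distance, exact binomial interval 85.1 to 86.3%).

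**Figure D4:**
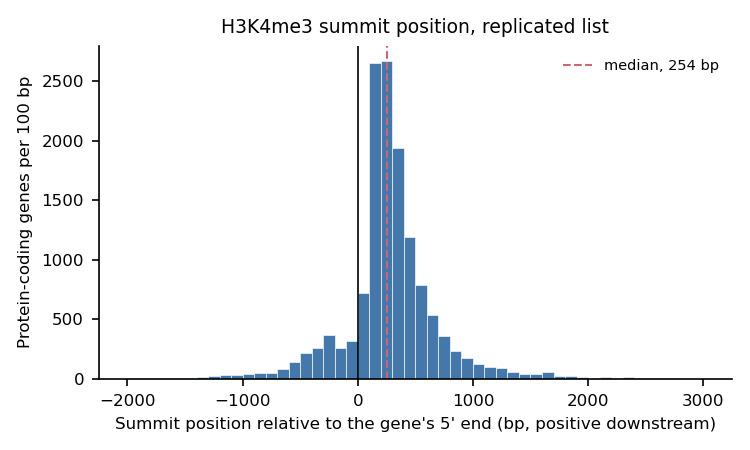
Position of the authors' peak summit relative to the gene's 5′ end in bp (x axis, positive downstream) for protein-coding genes with a replicated peak there, as the number of genes per 100 bp (y axis). The dashed line marks the median, 254 bp downstream, and the solid line the 5′ end.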

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

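The test of another cell type in replicate 1 was chosen only after the result was seen; the comparison without merging at midbrain genes was fixed earlier, but its reading as a test of cause was chosen after. The design has 1 group, so it names no biological difference that was tested, and cells of another type are weighed as a question of what the pools held.

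The pooled list held 17159 peaks outside the replicated list, a set that the comparisons above use only as an alternative. They were weak, with a median signal value of 2.43, a highest of 4.62 and a median width of 238 bp, and 22.7% lay at promoters. Of these peaks, 10110 overlapped a peak of replicate 1 only, 1465 of replicate 2 only, 88 of both and 5496 of neither. They were the only pooled peaks at the promoters of 244 protein-coding genes.

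The replicated list also held 13 peaks on 6 unplaced or unlocalised scaffolds, which the comparisons with genes and with random placement leave out. Their median signal value was 12.9 (range 2.55 to 46.3), their median width was 871 bp, and 11 were overlapped in both replicates.

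The peaks of replicate 1 without a partner in replicate 2 may be calls near the threshold of a longer list, or may come from cells of another type in that pool. Of these peaks, 1.62% (324) lay at promoters of coding genes not called in replicate 2, but 77.6% lay outside promoters, where this test sees nothing, and only 273 coding genes were called in replicate 1 alone, so the share could not have been high. Genes of the 8 lists of other cell types were called in replicate 1 only in 15 cases and in replicate 2 only in 2, a share of 88.2% beside 85% of all coding genes called in a single replicate. When replicate 1 was shortened to its 34732 strongest peaks by p, 76.4% of them were overlapped, between the 80% set for the threshold explanation and the 70% set against it. Both explanations stay open: 13.2% of the 13599 peaks left out were overlapped but 8194 of those kept were not.

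Wide domains at midbrain and isthmus patterning genes could arise from the merging of neighbouring peaks, or from CpG-rich sequence and strong signal around these promoters. Merging is excluded as the whole cause: without it, the median still exceeded that of other genes by 5501.5 bp (8026 against 2524.5 bp, permutation test, adjusted p = 5e-05). CpG count and the quintile of signal value are excluded as the whole cause of the merged width. The 10000 matched lists shared the quintile of signal value and lay near in CpG count in 10 kb around the 5′ end. Their highest median was 8137 bp, against 16229 bp observed. They may account for part of it. The matched lists had a typical median of 4241 bp (95% range 3087 to 5962 bp), above the 2646 bp of other marked genes. CpG sequence farther from the 5′ end was not matched. Signal value was not matched within a quintile, so its differences there stay open as a cause. No matched lists were drawn without merging, so merging and CpG content acting together stay open. The size of the difference depends on merging, and the level of transcription, which these data do not measure, stays open.

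Replicated peaks outside promoters could mark start sites missing from the annotation, or could be spread from a neighbouring promoter peak. Start sites that RefSeq lists are excluded as the main cause, since 8.69% (1090 of 12543) had one within 1 kb. RefSeq had 76277 sites, 16598 of them more than 1 kb from those of the annotation used. Shifted lists reached 5.85% at most, but shifted peaks could land on any of these sites. The observed peaks were chosen outside promoters, away from most of them, so 5.85% is too high a baseline and understates the excess. Start sites missing from both annotations were not searched and stay open. Spread stays open: 21.7% (2721) lay within 3 kb of a promoter peak, below the 50% the explanation needs for most peaks. Shifted lists reached 7.22% at most, which is also too high a baseline, since shifted peaks could land on the promoter peaks themselves. Weak calls were not tested as a cause. Of these peaks, 82.2% (10308) had a −log10 q of at least 5, but the median signal value of all 12543 was 4.25, against 40.8 for promoter peaks.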

How the results depend on the processing

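Alternatives chosen after the data were seen are the basic transcript set, summits within 1 kb, genes called in both replicates, and no merging in comparisons between lists. A tested result counted as kept when it had the same direction and side of the threshold, a value without a test when it moved by less than the spread between replicates (for the correlation, its 95% interval over peak pairs), and a count of lists when it stayed within 1.5 times. By these criteria 29 of 50 results were kept under every alternative run, and 300 of 348 alternatives kept theirs. Promoter share ranged from 45.2 to 63.9%, the marked share of coding genes from 65.6 to 68.5%, and the midbrain width difference from 5501.5 to 15046.5 bp. Values below are list minus other genes, in percentage points of marked share or bp of median width; the cause of each change was not tested. With a −log10 q of at least 5, shares became −0.459 for endothelial and −9.99 for pluripotency genes, and widths −1050.0 for glia, 380.0 for endothelial and −1017 for pluripotency genes. With 500 bp windows, shares became −31.6 for muscle and −9.77 for pluripotency genes, and the width difference between the Hox lists −6. With 2 kb windows the share of Hox groups 1 to 5 became 5.22. In the pooled list the Hox shares became 18.2 and 14.8. With the basic set, shares became 0.307 (Hox 1 to 5), −31.1 (muscle) and −9.22 (pluripotency), widths −1425 (muscle) and −1039 (pluripotency), and 2 lists in place of 4 were narrower. With summits within 1 kb, shares became 22.6 (midbrain), 17.7 (early neuron), 23.3 (forebrain), 1.06 (Hox 1 to 5) and −30.3 (muscle), and 3 lists in place of 6 were higher. For genes called in both replicates they became −31.8 (muscle) and −2.80 (pluripotency). Without merging, widths became −954 (glia), −1273 (erythroid) and 238.5 (mesenchyme), and the Hox difference −111. With merging across 3 kb they became 66 (endothelial), −1255.5 (muscle) and −1413.5 (pluripotency), and 2 lists were narrower; without merging 6 were. The Spearman correlation of peak strength was 0.936 with −log10 p and 0.929 with 50% overlap. For genes with a single start site the summit lay at 227.5 bp, downstream in 86.4%.

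Leaving out each replicate in turn gave shares of 6.03 to 11.7 (Hox 1 to 5), −4.81 to 6.68 (Hox 6 to 13), −7.31 to 5.01 (glia), −32.0 to −15.4 (muscle) and −3.02 to 3.10 (pluripotency), widths of −965 to −295.5 (erythroid) and −1447.5 to −924.5 (pluripotency), and summits downstream in 84.7 to 85.3%. Of 26 named unmarked genes, 8 became marked in replicate 1 alone, 6 in the pooled list and 4 in replicate 2 alone. Named domain widths moved beyond the replicate spread for 42 of 52 genes without replicate 1 and 21 of 54 without replicate 2. The spread is the SD of the same 2 replicate widths. These counts therefore mostly reflect which replicate the replicated width lay nearer to, and do not measure how stable each gene is. Without merging 30 of 57 moved, with merging across 3 kb 7 of 57, and with a −log10 q of at least 5, 3 of 57. With the basic set 0 of 53 did. No paired analysis was possible because there is 1 group. Liver, myeloid and germline genes had too few marked members for a width test. Depth is unknown, so an unmarked promoter was one not called in these lists.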

Other observations

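The comparison of the X chromosome with the autosomes, the matched widths of lists other than the midbrain list and the counts per chromosome were chosen only after the data were seen; the test of start sites at distal peaks was not.

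Genes on the X chromosome were marked less often than autosomal ones in these pools of both sexes. With chemosensory receptors left out, 495 of 939 coding genes on the X (52.7%) and 14286 of 19335 on autosomes (73.9%) had a replicated promoter peak (two-sided Fisher's exact test, p = 1.15e-41). Marked X genes had a median width of 2238 bp and a median signal value of 31.1, against 2669.5 bp and 48.8 on autosomes. No adjustment was made for CpG ratio, for other gene families or for the number of X copies, and the cause was not tested. With all coding genes counted, the autosomal share was highest on chromosome 12 (80.9%) and lowest on chromosome 7 (56.5%), and on the Y 4 of 183 genes (2.19%) were marked.

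Domains of replicated peaks numbered 26107, with a median width of 1643 bp. At least 5 kb was reached by 1397 of them, at least 10 kb by 185 and at least 20 kb by 19. Each list was also set against 10000 lists matched on CpG count and on the quintile of signal value. The progenitor median of 8025.5 bp lay above the highest matched list (6444.5 bp). So did the ventral midbrain median of 8299.5 bp (6521.5 bp) and the early neuronal median of 4640.5 bp (3850.0 bp). The posterior Hox median of 1049 bp lay below the lowest matched list (1134 bp), and the anterior Hox median of 1055 bp at the 0.04 percentile. Housekeeping genes lay at the 99.98 percentile, forebrain genes at the 99.5, mesenchymal genes at the 98.8 and muscle genes at the 0.69. Erythroid (97.15), endothelial (90.1), mature synapse (88.4), glial (26.1) and pluripotency genes (3.48) lay within the central 95% of their matched lists. Across marked coding genes, which are not independent replicates, CpG count and domain width had a Spearman correlation of 0.553.

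The strongest peaks far from annotated starts may mark start sites missing from the annotation used. Of the 100 strongest replicated peaks more than 10 kb from a start site, 33 had a RefSeq start site within 1 kb, against 439 of the other 5525 (7.95%), an odds ratio of 5.71 (Fisher's exact test, p = 1.53e-12). Among the 5 strongest, 3 had one. The median CpG ratio was 0.679 in the strongest and 0.330 in the others. The result is consistent with missing start sites for part of the strong distal peaks; the rest of the 100 stay without one.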
